A study of Mus musculus with 2 samples.

How the data were processed

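Histone H3 trimethylated at lysine 4 (H3K4me3), a chromatin mark of active and poised promoters, was measured by chromatin immunoprecipitation and sequencing in hearts of mice on postnatal day 0. The labels describe 2 biological replicates of a single group. Replicate 1 was a pool of 15 mice, and the number of mice in the pool of replicate 2 was not given in the sources used here. Both pools were of mixed sex and of a C57BL/6N strain, and library fragments measured 300 to 500 bp per the labels. No treatment, control tissue or other age was part of the design, so no difference between conditions was tested.

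The deposited files were peak lists in narrowPeak format on the mm10 build. The authors called peaks on each replicate alone and on the replicates pooled, each time against a control library, per the file descriptions that came with the deposit. A further deposited list holds replicated peaks, derived from the pooled list and both replicate lists. The aligner, the peak caller, its version, its threshold and the rule behind the replicated list were not given in the sources used here. The signal value of each peak is a fold enrichment over the control, a linear ratio computed by the authors' peak caller. The deposited significance values of each peak are −log10 p and −log10 q, also from the authors' caller. The smallest deposited −log10 p was 2.05 in replicate 1, 2.11 in replicate 2, 2.01 in the pooled list and 2.37 in the replicated list. These values belong to single peaks and were used only to describe, rank or filter peaks within a list. Read counts were not part of the files used, so the sequencing depth is unknown, and the number of peaks called in a replicate may not be read as a measure of its depth.

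Peaks were matched to the GENCODE mouse annotation M21 of GRCm38, the assembly that mm10 denotes, and every peak ended inside its chromosome in the GRCm38.p6 sequence. Coordinates are 1-based. A peak overlapped a peak of another list when they shared at least 1 bp, and the overlap was compared with 100 random placements of the peaks on their own chromosomes outside assembly gaps. A gene was called marked when a peak lay within 1 kb of any of its annotated transcription start sites (TSSs). Replicated peaks separated by gaps of up to 1 kb were merged into domains, and a gene's domain was the widest within 1 kb of a TSS. Protein-coding genes on the autosomes, X and Y were used (21938 genes), and 13 genes of the mitochondrial chromosome were left out. Replicate values of a domain width were computed the same way from each replicate's own list and are given as mean ± SD (n = 2). Wilson intervals at 95% are given for shares of peaks or genes, and exact binomial intervals for short lists. For a count of 0 the limit given is 3 counts over the total. Such intervals cover counting error alone.

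The design had no contrast, so gene lists were compared with other genes. In all, 21 lists holding 313 distinct genes were fixed before the data were examined. They covered sarcomere, cardiac transcription factors, calcium handling and conduction, natriuretic and atrial, ventricular, fatty acid oxidation and mitochondrial, cell cycle, endothelial and endocardial, fibroblast, valve and epicardial, mural and smooth muscle, macrophage and leukocyte, erythroid, Schwann and autonomic neuron, lung and thymus, liver, brain, skeletal muscle, epidermis and gut, Hox, housekeeping and sex-linked genes. Marked shares were compared with Fisher's exact test, two-sided, and median domain widths of lists with at least 3 marked members with 10000 random lists of marked genes of the same size (permutation p, two-sided). Membership in the broadest 5% of domains was tested with Fisher's exact test. Benjamini-Hochberg adjustment was made over the lists for each of these tests at a threshold of 0.05. Genes are not replicates, so these p-values describe the lists in these 2 pools. The smallest p that the random lists can give is 0.0002. Genes named in the text were 14 fixed landmarks, the genes of the 10 broadest domains (1 gene per domain, the one whose TSS lay nearest the centre), and per list the 2 members with the broadest domains and the first 2 unmarked members in alphabetical order. Cd8a, Cd3e, Lck, Rhoh, Cd8b1, Themis, Satb1, Bcl11b, Rag2 and Dntt were named for their state in the separate replicates, after it was seen. Some further genes are named only as members of lists or families. The T-lineage, B-lineage, myeloid, thymic epithelium and neuron lists were added after the replicates had been compared. When the T-lineage list was written, 8 of its 24 genes had been seen among those marked in replicate 1 alone, so tests on it used the other 16.

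The alternatives set before the data were examined were a −log10 q of at least 5 or 10, stricter overlaps, the pooled list, either replicate alone, other TSS windows, the 5'-most TSS, protein-coding TSSs, other distal limits, other gaps, random lists matched on the decile of promoter CpG count (within 500 bp of the TSS), and the broadest 10% of domains. An alternative restricted to replicated peaks overlapping a peak in each replicate was added after seeing the data. The share of promoter 31-mers found at another coding promoter was used to mark duplicated promoters (above 50%).

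The computations were tested on simulated data. Simulated peak sets of 1870 peaks that shared 50.7% or 81.1% were recovered at 51.9% and 81.9% with the 1 bp overlap. Among 200 simulated lists of 20 genes, 3.5% of unchanged lists passed Fisher's exact test for the marked share (21938 genes) and 5.0% passed the permutation test for the domain width (14765 genes). Domains scaled by 1.5 were detected in 91.0% of lists and by 2 in 99.5%. A marked share raised by 20 points was detected in 48.0% of lists and by 30 points in 99.0%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Peaks on contigs outside the assembled chromosomes were left out of the gene comparisons.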

Results

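H3K4me3 peaks were recorded in hearts of newborn mice, in 2 pools of animals that serve as biological replicates of a single group. Replicate 1 had 30987 peaks covering 37.0 Mb and replicate 2 had 29772 peaks covering 35.1 Mb. The pooled list had 31948 peaks covering 40.5 Mb, and the replicated list had 25525 peaks covering 38.6 Mb. The median peak was 873 bp wide in replicate 1, 900.5 bp in replicate 2 and 1277 bp in the replicated list. Fold enrichment is the authors' value for each peak over its control, and it had a median of 17.1 and a maximum of 92.1 among replicated peaks. Read depth is unknown.

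The first comparison asked how far the replicates marked the same places. Promoters of cardiac, endothelial and cell-cycle genes carried peaks in both pools, and 14591 protein-coding genes were marked in each. All 27 cardiac transcription factors and all 20 genes of calcium handling and conduction were marked in replicate 1 and again in replicate 2. Only 250 genes were marked in replicate 1 alone and 115 in replicate 2 alone. Genes of the T-cell lineage stood among the 250, including Rag1, which encodes the recombinase that assembles antigen receptor genes, as did Ptprc, the pan-leukocyte phosphatase CD45. Over all peaks, 25278 of 30987 replicate 1 peaks overlapped a replicate 2 peak, a share of 81.6% (95% Wilson interval 81.1 to 82.0), against 2.69% in random placements. In the other direction 87.1% of replicate 2 peaks overlapped (86.7 to 87.5), against 2.82% in random placements. Most peaks that were not shared were among the weaker ones. When each list was divided into 4 equal classes by −log10 q, 41.8% of replicate 1 peaks and 55.1% of replicate 2 peaks in the weakest class overlapped the other replicate, and 100% of both did in the strongest class. In the classes between, the shares were 84.7% and 99.8% in replicate 1 and 93.2% and 100% in replicate 2. Widths of the domains at genes marked in both replicates had a Spearman correlation of 0.928 across genes, which are not independent replicates. Where an overlap of at least 50% of both peaks was required, 71.4% of replicate 1 peaks and 74.4% of replicate 2 peaks were shared.

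**Figure D1:**
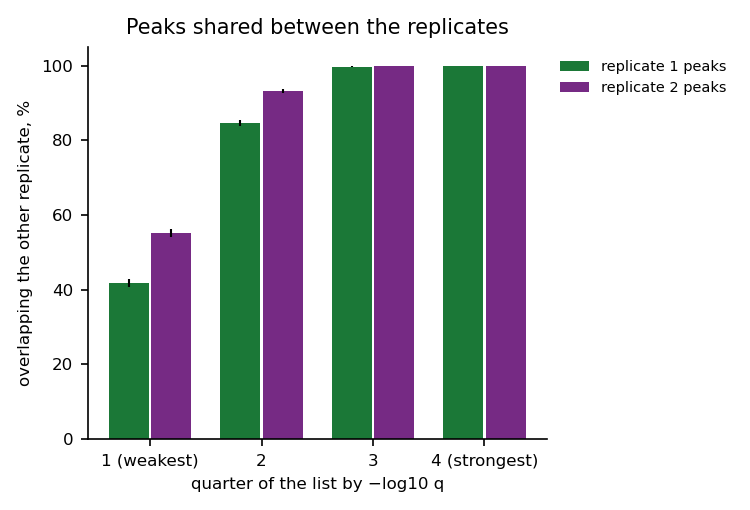
Share of each replicate's peaks that overlapped a peak of the other replicate (percent, y axis) in 4 equal classes of the list by −log10 q (x axis), with 95% Wilson intervals as bars. The share was 41.8% and 55.1% in the weakest class and 100% in the strongest class of both replicates.

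The second comparison asked what separated the replicated list from the pooled list. Domains of Hand2, Nkx2-5 and Myh6, described below, lost only short and weak peaks between the pooled and the replicated list. A pooled peak of 256 bp near Acta1, the skeletal alpha-actin gene, was dropped, so that Acta1 was the only sarcomere gene left unmarked. Of the 31948 pooled peaks, 25525 were kept, a share of 79.9% (79.5 to 80.3), and each kept row was identical in both lists. Dropped peaks had a median width of 258 bp and a median fold enrichment of 2.82, with a maximum of 5.31. Kept peaks had a median width of 1277 bp and a median fold enrichment of 17.1. Not every peak of the replicated list was present in both replicates by the overlap used here. Of its peaks, 23634 (92.6%) overlapped a peak in each replicate, 1210 overlapped replicate 1 alone, 612 replicate 2 alone and 69 neither. Rag1, Cd8a and Ptprc, each with a peak in replicate 1 and none within 1 kb of a TSS in replicate 2, were marked in the replicated list.

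Replicated peaks were concentrated at promoters. Of 25516 peaks on the assembled chromosomes, 17231 lay within 1 kb of an annotated TSS, a share of 67.5% (67.0 to 68.1), against 10.3% in random placements. These promoter peaks had a median width of 1715 bp and a median fold enrichment of 32.5. Another 14.5% of peaks lay in introns, 3.24% in exons and 14.8% between genes, with median fold enrichments of 4.53, 6.05 and 5.92. The share at promoters was 58.6% in the pooled list, which holds the weak peaks that the replicated list lacks.

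Of 21938 protein-coding genes, 14765 (67.3%, 66.7 to 67.9) were marked in the replicated list, 14841 in replicate 1 and 14706 in replicate 2. Gene families of general cell function were marked almost in full. All 76 cytosolic ribosomal protein genes, all 78 mitochondrial ribosomal protein genes and all 37 genes of complex I, the first enzyme of the respiratory chain, carried a peak, as did 39 of 40 proteasome subunit genes. Sensory receptor families were almost unmarked, with 5 of 1135 olfactory receptor genes and 1 of 331 vomeronasal receptor genes. Of 42 beta-defensin genes, which encode antimicrobial peptides of epithelia, 0 were marked, which allows a share of up to 7.14%. Among non-coding genes, 931 of 5854 lincRNA genes (15.9%) and 1092 of 2959 antisense genes (36.9%) were marked.

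The next comparison asked which genes carried the broadest H3K4me3 domains. Several transcription factors of the heart were among them. Hand2, a factor of right ventricular development, had the broadest domain at 18721 bp (chromosome 8, 57311164 to 57329884). It covered the whole gene and reached 9819 bp upstream, and its width in the replicates was 21506 ± 4734 bp (SD, n = 2). Gata4, a factor of early heart formation, had a domain of 18091 bp (chromosome 14, 63234872 to 63252962; replicates 17884 ± 210.0 bp, n = 2). That domain lay 18730 bp inside the gene, counted from its 5'-most annotated TSS. Nkx2-5, the homeobox factor of the cardiac lineage, had 17577 bp over its full length and 8387 bp upstream (chromosome 17, 26835820 to 26853396). The replicates gave 14121 ± 4931 bp (n = 2). Gata6, which acts with Gata4 in the heart, had 16770 bp (chromosome 18, 11047707 to 11064476), and Irx5, an Iroquois factor of ventricular repolarisation, had 13990 bp (chromosome 8, 92353157 to 92367146). Nr2f2, a factor of atrial and venous identity, had 17976 bp (chromosome 7, 70350045 to 70368020), but its replicates had the largest SD in this group, at 17684 ± 6146 bp (n = 2).

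Myh6, the adult atrial and ventricular alpha-myosin heavy chain gene of the mouse, was the only structural gene among the 10 broadest domains when each domain is given to 1 gene, with 16580 bp (chromosome 14, 54956271 to 54972850; replicates 17685 ± 1776 bp, n = 2). The domain covered 42.6% of the gene body and 5923 bp upstream. It also reached an internal annotated TSS of the neighbouring beta-myosin gene Myh7, whose listed domain is therefore the same interval. With the 5'-most TSS, the Myh7 domain was 10407 bp. The remaining genes so counted were Nfib at 17471 bp, Meis2 at 16886 bp and Ebf3 at 14617 bp, which encode transcription factors used in many tissues. The median over all marked genes was 2037 bp, and 30 genes exceeded 10 kb. Merging gaps set several of these widths: without merging, Nkx2-5 fell to 7391 bp, Nr2f2 to 8751 bp and Myh6 to 10712 bp. With the 5'-most TSS alone, Gata4 had 7802 bp, and Nfib had no domain. The first place also depended on the setting. It went to Nfib without merging (14453 bp, Hand2 13355 bp), to a domain of the Hoxa cluster with gaps of 3 kb (27083 bp, Hand2 23784 bp), to Myh6 in the pooled list (19027 bp) and to Nr2f2 in replicate 2 alone (22030 bp, Hand2 18159 bp). In replicate 2 alone Nkx2-5 had 10634 bp and Meis2 9916 bp, and in replicate 1 alone Ebf3 had 7171 bp. Without merging, 18 of the 53 marked genes named by rule changed in width by over 1.5 times.

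**Figure D2:**
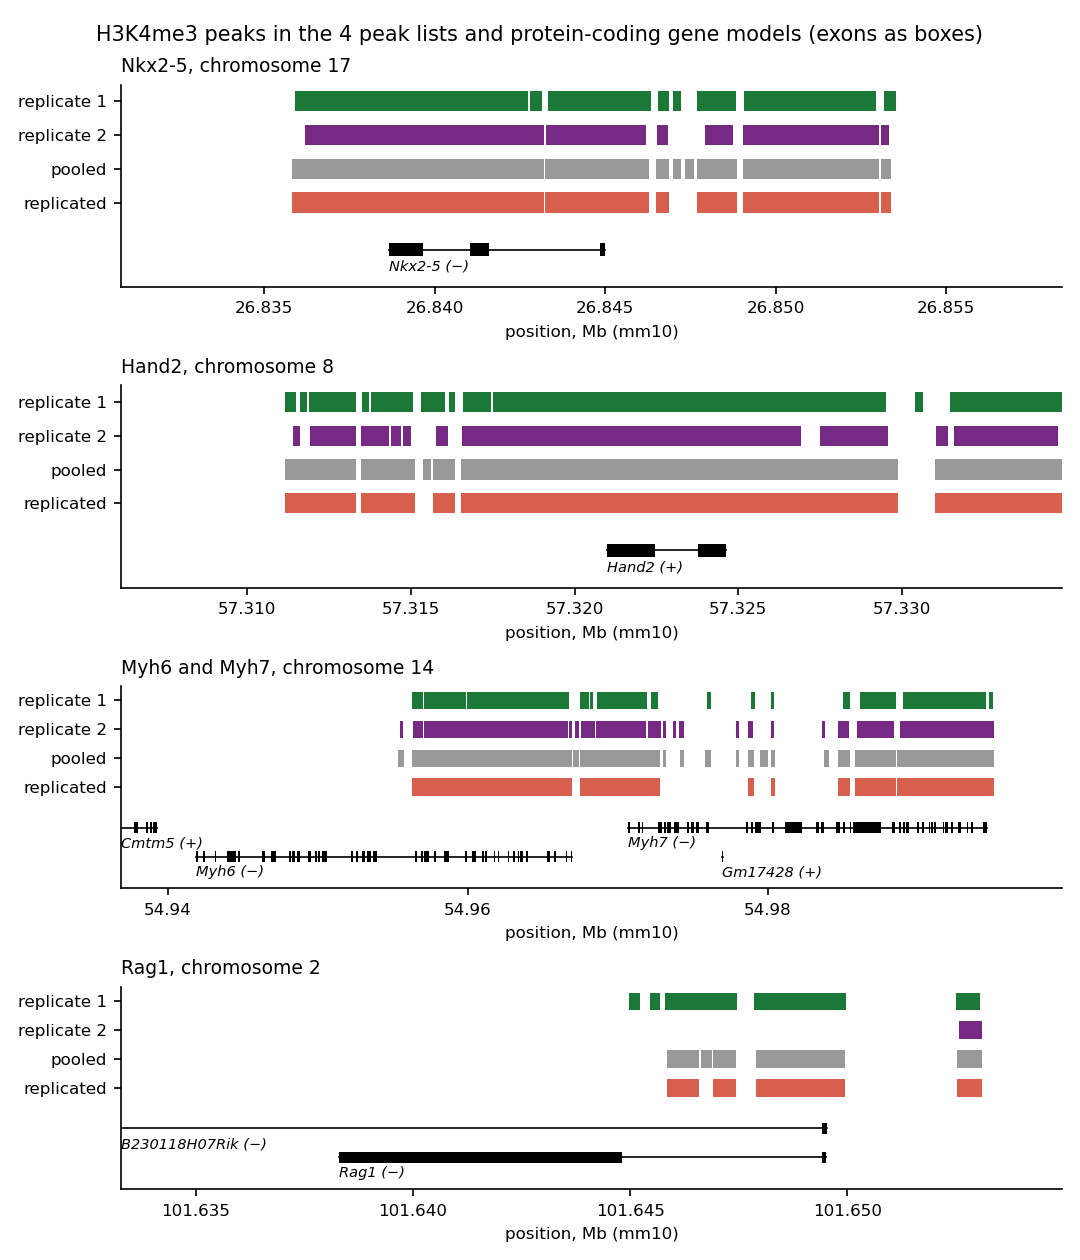
Peaks of replicate 1, replicate 2, the pooled list and the replicated list (bars) around Nkx2-5, Hand2, Myh6 with Myh7, and Rag1, along each chromosome in Mb (mm10), with protein-coding gene models below and the strand in brackets. Both replicates covered the first 3 regions, while at the Rag1 promoter replicate 1 and the replicated list had peaks and replicate 2 had none.

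The gene lists then gave marked shares and domain widths for genes of each cell type and process. Genes of the contractile apparatus were marked and broad. Of 25 sarcomere genes 24 were marked (96.0%), 28.7 points above other genes (adjusted p = 0.00256, Fisher's exact test). Their median domain of 5195 bp was 2.55 times that of all marked genes (replicates 5212 ± 279.0 bp, SD, n = 2; permutation adjusted p = 0.00076), and 14 of 24 fell in the broadest 5% of domains, which began at 4739 bp. Myl2, the ventricular regulatory light chain, had 7525 bp, and Tnnt2, cardiac troponin T, had 6948 bp. Cardiac transcription factors were all marked (27 of 27), with a median of 7035 bp and 22 genes in the broadest 5%. Tbx5, a factor of chamber and limb patterning, had 10422 bp (replicates 10446 ± 146.4 bp, n = 2). CpG-matched lists were marked at 95.2%, so near the ceiling that the test could not show a higher share (permutation adjusted p = 0.748). The breadth of this list exceeded that of CpG-matched lists (permutation adjusted p = 0.000633, the smallest the 10000 lists gave after adjustment).

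Calcium handling and conduction genes were also marked in full (20 of 20, adjusted p = 0.00148, Fisher's exact test), with a median domain of 4757 bp and 10 genes in the broadest 5%. Gja1, the gap junction protein connexin 43, had 9756 bp, Slc8a1, the sodium-calcium exchanger, had 9700 bp, and Ryr2, the calcium release channel of the sarcoplasmic reticulum, had 8070 bp. Scn5a, the cardiac sodium channel, was narrow by comparison at 2212 bp. The 6 ventricular genes were all marked and had a median of 6435 bp, with Hey2, a repressor of atrial genes, at 7646 bp (permutation adjusted p = 0.00076 for the width). All 6 also belong to other lists: Myl2, Myl3 and Myh7 to sarcomere, Irx4 and Hey2 to cardiac transcription factors, and Nppb to natriuretic and atrial. The width counted for Myh7 is that of the Myh6 domain. The ventricular breadth is therefore not separate from that of the other lists. The 11 natriuretic and atrial genes were all marked too, but their median of 2162 bp did not differ from other marked genes (permutation adjusted p = 0.823). Nppa, the atrial natriuretic peptide gene, had a weak domain of 2162 bp with a fold enrichment of 4.50 (replicates 1582 ± 598.9 bp, n = 2; 1158 bp in replicate 2 alone). The higher marked share of the atrial list (adjusted p = 0.0332, Fisher's exact test) was lost at a −log10 q of at least 5 (adjusted p = 0.151) and of at least 10 (adjusted p = 0.360).

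Metabolic and housekeeping genes were marked without exception. All 22 genes of fatty acid oxidation and mitochondria carried a peak, and their median domain was 3076 bp (permutation adjusted p = 0.00475). Hadha and Hadhb, the subunits of the mitochondrial trifunctional protein that are encoded head to head, had 1 domain of 8390 bp between them (2840 bp without merging, 3526 bp at a −log10 q of at least 10). All 20 housekeeping genes were marked with a median of 3010 bp (permutation adjusted p = 0.0038), the broadest being Hnrnpa2b1 at 5691 bp and Gapdh at 5128 bp. All 20 cell-cycle genes were marked, and their median of 2430 bp did not differ from that of other marked genes (permutation adjusted p = 0.245), although the D-type cyclins Ccnd2 and Ccnd1 had 7538 and 6408 bp. The breadth of the metabolic list was lost when the 5'-most TSS alone was used (median 2642 bp, permutation adjusted p = 0.0769). All genes of the cell-cycle and housekeeping lists were marked, against 97.9% and 98.1% in CpG-matched lists (permutation adjusted p = 1 for both). Shares so near the ceiling left this test no room to show an excess.

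Genes of other cell types of the heart were compared in the same way. All 16 endothelial and endocardial genes were marked (adjusted p = 0.00564, Fisher's exact test), with a median domain of 4962 bp and 10 genes in the broadest 5%. Nfatc1, a factor of endocardial cushion development, had 9480 bp, with replicates at 6963 ± 3184 bp (n = 2; 4711 bp in replicate 1 alone), and Fli1, an endothelial and blood ETS factor, had 8768 bp. Of 16 fibroblast, valve and epicardial genes 14 were marked, with a median of 3570 bp (permutation adjusted p = 0.00253). Pdgfra, a receptor of cardiac fibroblasts, had 9088 bp and Wt1, a factor of the epicardium, had 8767 bp (4150 and 5448 bp without merging), while the mesothelial genes Msln and Upk3b were unmarked. The marked share of that list did not pass Fisher's exact test (adjusted p = 0.144). All 10 mural and smooth muscle genes were marked, but neither the share (adjusted p = 0.0549, Fisher's exact test) nor the median width of 2613 bp (permutation adjusted p = 0.245) passed. The mural share passed in 4 of 10 alternatives, among them the 5'-most TSS (adjusted p = 0.0279, Fisher's exact test), and did not pass in the other 6. The broadest members of the mural list were Cspg4 at 3409 bp and Pdgfrb, the pericyte receptor, at 3168 bp. Against CpG-matched lists, both the fibroblast list (56.7% in matched lists, permutation adjusted p = 0.00252) and the mural list (57.8%, adjusted p = 0.0072) were marked more often, and the mural width passed (permutation adjusted p = 0.0203).

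**Figure D3:**
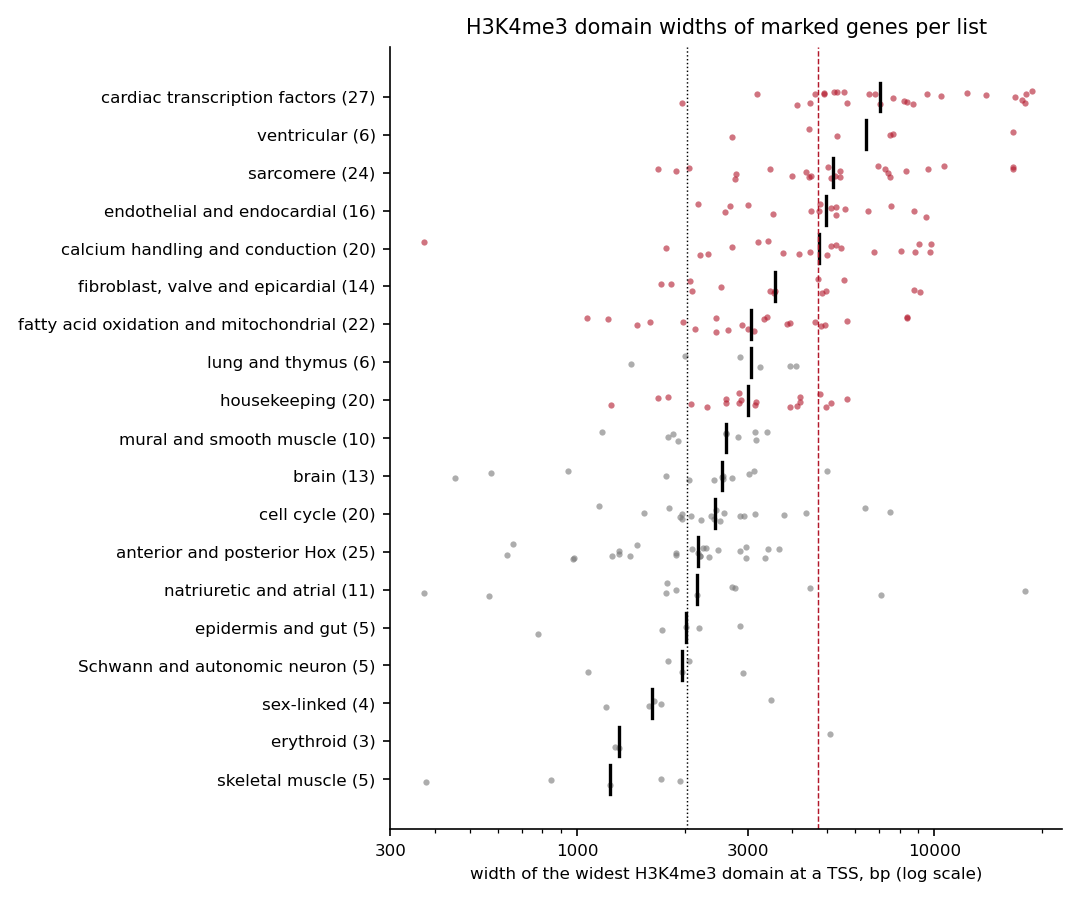
Width of the widest replicated H3K4me3 domain at each marked gene (points, bp on a log scale), by gene list with the number of marked genes in brackets. Black bars are list medians, the dotted line is the median of all marked genes (2037 bp), the dashed line is the start of the broadest 5% (4739 bp), and red marks the 8 lists that were broader than random lists.

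Macrophage and erythroid genes were marked less often than other genes. Of 12 macrophage and leukocyte genes, 1 was marked (8.33%), a difference of -59.0 points from other genes (adjusted p = 0.000401, Fisher's exact test). The marked gene was Ptprc, with 1647 bp, and the macrophage genes Adgre1 and C1qa had no peak. Ptprc was marked by replicate 1 (3566 bp) and had no peak in replicate 2. Of 11 erythroid genes 3 were marked (27.3%, adjusted p = 0.0148, Fisher's exact test), among them Tal1, a factor of blood and endothelial precursors, at 5089 bp and Gypa, the red cell surface protein glycophorin A, at 1314 bp. Alas2, the first enzyme of haem synthesis in red cells, and Epb42 were unmarked. Both lists have CpG-poor promoters, and their shares did not pass against CpG-matched lists, which were marked at 20.2% and 25.9% (permutation adjusted p = 0.801 and 1). With so few genes and such low matched shares, this test had little room to show a lower share. It does not decide whether CpG density accounts for the deficit.

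The lung and thymus list was split. Of its 12 genes 6 were marked in the replicated list, 7 in replicate 1 and 3 in replicate 2. Nkx2-1, a lung and thyroid factor, was marked in both replicates at 3791 ± 235.5 bp (n = 2). Rag1 had a domain of 4103 bp in the replicated list (chromosome 2, 101645846 to 101649948, at a promoter shared with the gene model B230118H07Rik) and of 5004 bp in replicate 1, with no peak in replicate 2. Cd8a and Cd3e, surface proteins of T cells named here because they were marked in replicate 1 alone, had 4012 and 2300 bp there, while the T-cell kinase gene Lck was marked in both replicates at 2892 and 1615 bp. Ptcra, the pre-T-cell receptor chain, had 718 bp in replicate 1 alone. Foxn1, the factor of thymic epithelium, was unmarked. In the replicated list the marked share did not differ from other genes (adjusted p = 0.248, Fisher's exact test). Without replicate 1 it differed by -42.1 points (adjusted p = 0.00674, Fisher's exact test), a share of 25% that did not pass against the 43.0% of CpG-matched lists (permutation p = 0.145), and with replicated peaks that overlapped both replicates by -41.6 points (adjusted p = 0.00754), an alternative chosen after seeing the data.

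Of the lists of other tissues, liver and skeletal muscle were marked less often than other genes. Liver genes were marked in 2 of 12 cases (adjusted p = 0.00148, Fisher's exact test), with Alb, the albumin gene, and Ahsg unmarked. The marked members were Apoh at 3232 bp and Trf, transferrin, at 871 bp. Skeletal muscle genes were marked in 5 of 16 cases (adjusted p = 0.0108, Fisher's exact test). Myod1, the master factor of skeletal muscle, had a narrow replicated peak of 378 bp found in replicate 2 alone, and Myf5 and Mybpc1 had none. Epidermis and gut genes were marked in 5 of 12 cases (adjusted p = 0.0964, Fisher's exact test) and Schwann and autonomic neuron genes in 5 of 10 (adjusted p = 0.312), with Phox2b and Dbh unmarked. The epidermis and gut list was marked less often, past the threshold, in 5 of 10 alternatives (-38.8 points with the 5'-most TSS, adjusted p = 0.0225, Fisher's exact test), but by -2.11 points against CpG-matched lists (permutation adjusted p = 1). The shares of liver (-19.1 points) and skeletal muscle (-17.2 points) lay below those of CpG-matched lists but did not pass (permutation adjusted p = 0.333 for both).

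Most brain and Hox genes were marked, and with gaps of 1 kb they were not broader than other marked genes. Of 15 brain genes 13 were marked (86.7%, adjusted p = 0.206, Fisher's exact test), with a median domain of 2542 bp that did not pass the test (permutation adjusted p = 0.245). Pax6, a factor of eye and brain, had 5020 bp (1145 bp with the 5'-most TSS), Neurod1 had 455 bp, and Gfap and Slc17a6 were unmarked. Of 28 Hox genes 25 were marked (89.3%, adjusted p = 0.0243, Fisher's exact test), with a median of 2178 bp (permutation adjusted p = 0.67) and 0 in the broadest 5%. Hoxa1 and Hoxa2 were the broadest at 3670 and 3420 bp, and Hoxb1 and Hoxc12 were unmarked. In replicate 1 alone Hoxa1 and Hoxa2 shared a domain of 8331 bp, and 2 Hox genes fell in the broadest 5%. The Hox call was lost in Fisher's exact test at a −log10 q of at least 10 (adjusted p = 0.322) and with the 5'-most TSS (adjusted p = 0.284). Against CpG-matched lists the Hox difference turned to -4.81 points (permutation adjusted p = 0.748). The Hox width turned with the gap that was merged. It was 1465 bp without merging (narrower, permutation adjusted p = 0.0152) and 3362 bp with 3 kb (broader, permutation adjusted p = 0.00253). With 3 kb, 7 Hox genes fell in the broadest 5% (adjusted p = 0.000791, Fisher's exact test). There the listed Hoxa3, Hoxa9 and Hoxa10 shared 1 domain of 27083 bp, and Hoxa1 and Hoxa2 shared another of 11454 bp. Both tests counted genes of a shared domain separately, so these p-values overstate the number of separate domains.

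**Figure D4:**
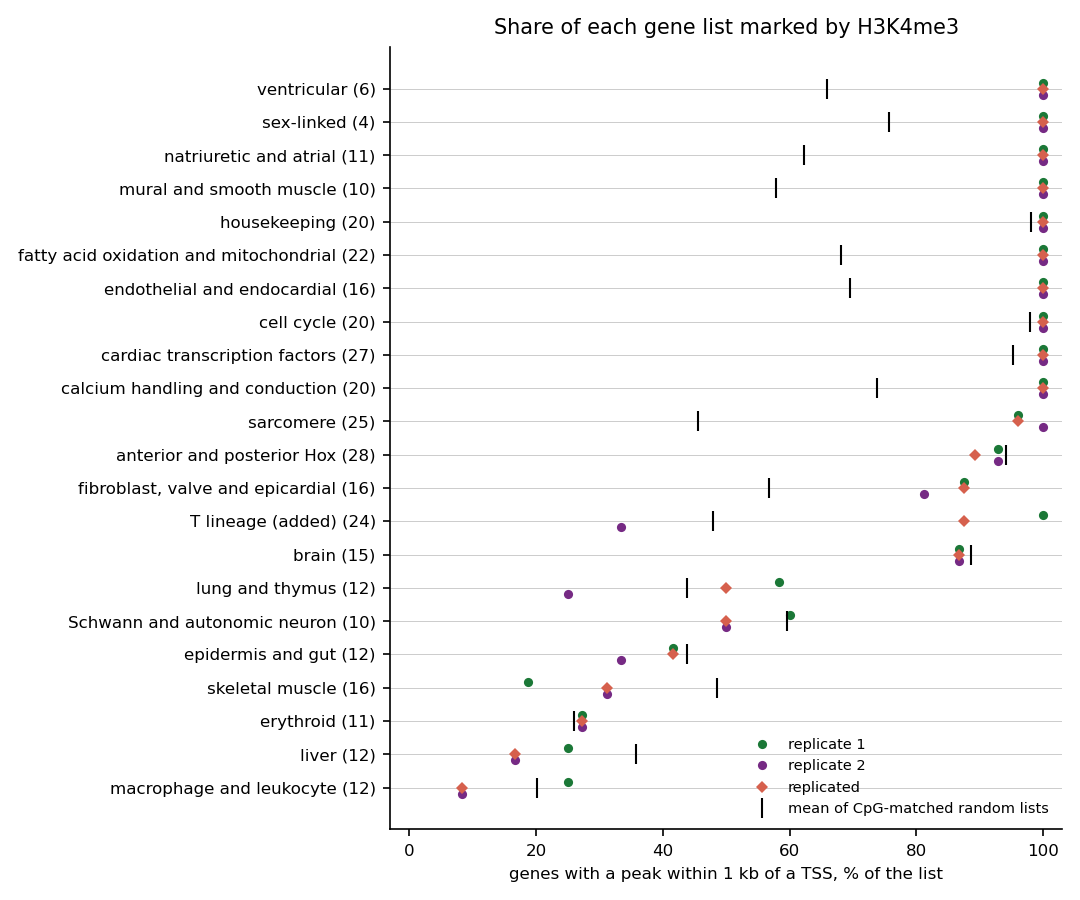
Share of each gene list with a peak within 1 kb of a TSS (percent, x axis) in replicate 1, replicate 2 and the replicated list, with the mean of CpG-matched random lists as a bar and the number of genes in brackets. The T-lineage list, added after the replicates had been compared, was marked at 100% in replicate 1 and 33.3% in replicate 2.

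Over the 21 lists, 9 were marked more often and 4 less often than other genes, and of 19 tested for width 8 were broader and 0 narrower (1 at an unadjusted permutation p under 0.05). The lists are not independent: all 6 ventricular genes and most natriuretic and atrial genes also belong to other lists. Against CpG-matched random lists 7 lists were marked more often, including 5 of the 9 above, and 10 were broader, including all 8 above. The fibroblast and mural lists were gained for the share. The mural and the lung and thymus lists were gained for the width (lung and thymus, permutation adjusted p = 0.0437). The marked lung and thymus genes include Rag1, Cd8a and Cd3e, which had no replicate 2 peak at a TSS. Nkx2-1, Foxj1 and Lck were marked in both replicates. In replicate 2 alone the median of that list was 1799 bp. None was marked less often, but short lists with low matched shares had little room for that.

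The chromosomes differed in their marked shares. On the X chromosome 497 of 948 protein-coding genes were marked (52.4%, 49.2 to 55.6), against 14264 of 20807 autosomal genes (68.6%, 67.9 to 69.2). The difference of -16.1 points passed Fisher's exact test (p = 6.57e-24), and the shares in the separate replicates were 52.6% and 52.0% on the X. Against autosomal sets matched on promoter CpG -2.56 points remained (permutation p = 0.0096), and with duplicated promoters left out as well the difference turned to 2.21 points (permutation p = 0.0366). Xist, the RNA that silences an X chromosome in females, had a domain of 3495 bp, and 4 of 183 Y-linked genes were marked. Ddx3y, a Y-linked RNA helicase gene, had 1719 bp, in pools that the labels give as mixed in sex. The 4 protein-coding genes of the sex-linked list were all marked, with a median domain of 1616 bp, and neither the share (adjusted p = 0.312, Fisher's exact test) nor the width (permutation adjusted p = 0.394) passed.

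Distal peaks formed the last comparison. Of the replicated peaks 5271 lay more than 5 kb from any TSS, a share of 20.7% (20.2 to 21.2) against 73.4% in random placements. Their median width was 611 bp and their median fold enrichment 5.31, both below those of promoter peaks (1715 bp and 32.5). Some merged domains far from annotated TSSs were broad nevertheless. A domain of 6737 bp lay 15273 bp from the nearest TSS, that of Lncppara, and 59358 bp from that of Ppara, a regulator of fatty acid oxidation. Another of 5866 bp lay inside Ostm1, 41459 bp from its nearest TSS, and a further domain of 6511 bp lay 95058 bp from Mir148a. These 3 were chosen after their values were seen. The distal share was 25.03% in the pooled list and 15.6% at a −log10 q of at least 10.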

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

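Replicated peaks also fell outside the assembled chromosomes, on sequence that the gene comparisons did not use. There were 9 such peaks on 5 contigs of mm10, with fold enrichments of up to 44.3. They are listed because the comparisons left them out, and no number of peaks on such contigs was expected beforehand. The replicates had 19 and 14 peaks on such contigs and the pooled list 16. The broadest was 2136 bp wide, and no explanation was tested for these peaks.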

How the results depend on the processing

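The lower marked share on the X chromosome kept its direction and passed in the 9 alternatives run for it (-16.7 to -15.2 points), none of which matched CpG density, where -2.56 points remained in a separate test and 2.21 points with duplicated promoters left out too. The counts of lists marked more often (7 to 10) and of lists with broader domains (7 to 10) stayed within 1.5 times of 9 and 8. Of 210 alternative values for the marked shares of single lists, 184 kept their direction and side of the threshold, as did 207 of 227 for list widths. Of 814 alternative widths of named genes, 653 moved by less than the SD between replicates or not at all. Both counts include named genes that were unmarked and stayed so, beyond the 53 marked ones, so 653 overstates how stable the reported widths were. Against CpG-matched lists the marked share turned for the erythroid (1.37 points), lung and thymus (6.17 points), brain (-1.92 points) and Hox lists (-4.81 points), and the width against its comparison turned for the epidermis and gut (2023 bp) and sex-linked lists (1616 bp). The Hox width turned from above to below its comparison at a −log10 q of at least 5 (1897 bp) and 10 (1865 bp), in the pooled list (1999 bp), with the 5'-most TSS (1859 bp), without merging (1465 bp) and with either replicate alone (1682 to 1792 bp). Other list widths turned with the 5'-most TSS (epidermis and gut, 2189 bp), without merging (Schwann and autonomic neuron, 1963 bp; brain, 1895 bp) and in 1 of the 2 replicates taken alone (natriuretic and atrial, 1706 to 2607 bp; lung and thymus, 1799 to 2892 bp; epidermis and gut, 1549 to 2055 bp). Of these turned widths only the Hox value without merging passed the threshold. Against CpG-matched lists the count of lists marked less often was 0 in place of 4, a test with little room for a lower share in the macrophage and erythroid lists. For these changes the cause was not tested.

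The remaining changes were in shares, in counts of lists and in single list widths, and for these too the cause was not tested. Skeletal muscle domains became narrower past the threshold in the pooled list (1041.5 bp, permutation adjusted p = 0.0131). Lung and thymus domains became broader past it against CpG-matched lists (3057.5 bp, permutation adjusted p = 0.0437). Their median was 1799 bp in replicate 2 alone, where Rag1, Cd8a and Cd3e had no peak at a TSS. At a −log10 q of at least 5, 91.0% of replicate 1 peaks and 93.5% of replicate 2 peaks overlapped the other replicate, 97.5% of pooled peaks were kept, 70.2% of peaks lay at a TSS and 19.3% were distal. At 10 or more these were 94.1%, 95.4%, 99.99%, 76.4% and 15.6%, with 65.9% of genes marked. With 50% of the peak covered the replicate overlaps were 77.2% and 83.1%, and with 50% of both peaks 71.4% and 74.4%. In the pooled list 58.6% of peaks lay at a TSS, 68.2% of genes were marked, 25.03% of peaks were distal and 2 lists had narrower domains. A TSS window of 500 bp gave 65.2% of peaks and 66.8% of genes, and 2500 bp gave 73.5% and 68.24%. The 5'-most TSS gave 63.8% of genes. Protein-coding TSSs alone gave 62.0% of peaks at a TSS and 28.0% distal. Distal peaks made up 26.5% beyond 2500 bp and 14.6% beyond 10 kb. Without merging, 1 list was narrower and 5 lists were over-represented among the broadest domains. With peaks that overlapped both replicates, an alternative added after seeing the data, 70.3% lay at a TSS, 66.6% of genes were marked and 19.2% of peaks were distal. With either replicate alone, 61.1% to 62.5% of peaks lay at a TSS, 21.4% to 22.4% were distal and 0 to 1 lists were narrower. No paired analysis was possible because there is 1 group. Unknown read depth limits every statement about an absent peak.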

Other observations

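Several non-coding loci outside the comparisons above carried broad domains, and they were chosen after their values were seen. Malat1, an abundant nuclear RNA, had a domain of 8515 bp (replicates 8802 ± 415.1 bp, SD, n = 2), and Neat1, the scaffold of paraspeckles, had 6532 bp. B230312C02Rik, at the locus of the muscle microRNA gene Mir1a-1, had 7781 bp with replicates at 7741 ± 61.5 bp (n = 2), 50807 bp from the nearest coding TSS. Carmn, a lincRNA of the smooth muscle and cardiac lineage, had 5013 bp with a lower fold enrichment of 9.69. In all, 544 marked lincRNA genes had their domain more than 1 kb from any coding TSS.

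Gene families gave the following values, and several of their members also belong to the lists above. Gata4, Gata5, Gata6, Tbx2, Tbx3, Tbx5, Tbx18 and Tbx20 are in the cardiac transcription factor list. Gata1 is in the erythroid list, and Sox17 and Sox18 are in the endothelial list. The family values thus partly repeat genes already reported. Of 6 GATA factors 5 were marked with a median domain of 10495 bp, and 18 of 19 Sox factors, 14 of 16 T-box factors and 39 of 44 forkhead factors were marked with medians of 3489, 2683 and 2646 bp. Of 394 genes of the Zfp series of zinc finger proteins 346 were marked, with a median of 1732 bp. Histone genes were marked in 57 of 67 cases with a median of 3627 bp. Keratin genes, which form the filaments of epithelia, were marked in 8 of 53 cases and cytochrome P450 genes in 25 of 100. These families were not tested against other genes.

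Blood and neural lists written after the replicates had been compared gave the following values. Of 24 T-lineage genes 24 were marked in replicate 1, 8 in replicate 2 and 21 in the replicated list. Rhoh, a signalling protein of lymphocytes, had 6579 bp in replicate 1, Cd8b1 5137 bp and Themis, a protein of thymocyte selection, 3923 bp, and none of these had a peak in replicate 2. The factors Satb1 and Bcl11b, which are also used outside the T lineage, were marked in both replicates, at 8539 and 8537 bp in replicate 1 and at 2838 and 4549 bp in replicate 2. B-lineage genes were marked in 4 and 3 of 12 cases in replicates 1 and 2, myeloid genes in 1 of 12 in both, and thymic epithelium genes in 7 of 8 in both, a share of 87.5% where CpG-matched lists gave 83.7% in replicate 1 (permutation p = 1). Neuronal genes were marked in 16 and 15 of 18 cases. Of the 250 genes marked in replicate 1 alone, 38 had domains above 2 kb, against 5 of the 115 marked in replicate 2 alone.

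In the paragraphs that follow, the tests of T-lineage cells, of peak calling in replicate 2 and of CpG density for brain and Hox genes were chosen only after the results were seen, and no group of the design gave a biological explanation to test. The first pattern was that T-lineage genes were marked in replicate 1 and less often in replicate 2. Weaker peak calling in replicate 2 was argued against: of the 16 listed genes not seen beforehand 8 lacked a replicate 2 peak, where lists matched on fold enrichment lacked 1.66 on average (permutation p = 0.0004). Blood cells in general were not decided by the myeloid list. Its share was 8.33% in both replicates, against 100% of these 16 in replicate 1 (p = 5.59e-07, Fisher's exact test, two-sided). CpG-matched lists differed too, at 36.8% and 52.1%, so this comparison mixes lists of unlike promoters. The myeloid share showed no gain in replicate 1, and B-lineage genes were marked in 4 and 3 of 12 cases. Macrophage and leukocyte genes, marked in 3 of 12 cases in replicate 1 and 1 in replicate 2, leave other leukocytes open. Cells of the T lineage in the replicate 1 pool remain a candidate explanation, as these 16, whose state had not been seen when they were listed, were marked at 100% there against 52.1% in CpG-matched lists (permutation p = 0.0002, the smallest these lists can give). The labels name no sort or gate, and the 8 of these 16 marked in replicate 2 were no more than in CpG-matched lists (50.8%, permutation p = 1). Whether such cells came from thymus or from blood was not decided by Foxn1, which was unmarked in both. Rag1, Rag2, Dntt and Ptcra, the pre-T-cell receptor chain, were marked in replicate 1 and not in replicate 2. Their bearing on that origin was not tested.

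The second pattern was the lower marked share of X-linked genes. X-linked promoters were poorer in CpG (median 27 against 51 within 500 bp of the TSS), and autosomal sets matched on CpG decile had a mean marked share of 55.0% (95% range 53.1 to 56.9) against 52.4% on the X. CpG density may thus account for most of the -16.1 points, but -2.56 points remained (permutation p = 0.0096). The autosomal share rose steeply over deciles 3, 4 and 5, from 22.4% to 59.2% and 92.7%. CpG differences within a decile were not matched, so this test does not decide whether CpG density was the whole cause. Duplicated promoters were more frequent on the X (19.7% against 4.29%). Without them the difference was -6.78 points (p = 7.59e-05, Fisher's exact test), so they were not the whole cause by themselves. With both taken into account X-linked genes lay 2.21 points above their matched sets (permutation p = 0.0366). The peak lists do not show how reads from duplicated promoters were placed.

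The third pattern was that brain and Hox genes were marked without broad domains when gaps of 1 kb were merged (with 3 kb the Hox list was broader). The Hox list was marked more often than other genes (89.3%, adjusted p = 0.0243, Fisher's exact test), and the brain list (86.7%) did not pass. Their CpG-rich promoters are consistent with how often they were marked: the marked shares lay -1.92 and -4.81 points from CpG-matched lists (permutation p = 1 and 0.417). Neurons in the pools cannot be told apart from that effect, because 83.3% of 18 neuronal genes were marked where CpG-matched lists gave 82.0% (permutation p = 1), a share near its ceiling. Whether these promoters also carried a repressive mark was not measured here.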
